A study of Mus musculus with 384 samples.

How the data were processed

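Single cells from mouse lung tumours were profiled by SmartSeq2, a plate-based RNA-seq method that copies full-length transcripts of 1 cell per well. The tumours arose in mice with inducible mutant Kras and deleted Trp53, after Cre delivery to the lung. Per the labels' protocols, live CD45+ CD3+ cells were sorted into 96-well plates. The labels put 192 cells in the control group and 192 in the group given G1T28, a CDK4/6 inhibitor, by mouth at 100 mg/kg daily. Each of 4 plates held control cells in well columns 1 to 6 and G1T28 cells in columns 7 to 12, so treatment and position on the plate went together. The labels name no animals and give the strain as a mixed background. Each treatment therefore counted as 1 sample. No p-value, standard error or count of changed genes was made from cells. SDs over cells describe the cells. The 4 plates are batches whose values stand beside the pooled ones, and whether they held different animals is not known.

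The authors deposited a table of log values of normalized expression plus 1 for 13576 genes in 245 of the 384 labelled cells, 121 control and 124 G1T28 cells, and a table with the treatment, plate, cell cycle phase and cluster of each cell. The submitters' processing notes name STAR and kallisto, with no versions, and the builds mm9 and hg19. What normalization was used, and how the phases and clusters were called, is not given in the sources used here. The deposited values were read as natural log values. The base was inferred from the values, since the largest set of identical profiles, shared by 47 genes, had a median of 0.6935 and the natural log of 2 is 0.6931. A difference of 0.69 in this unit is thus about a doubling on the normalized + 1 scale. The treatment column of the deposited table matched the labels in 245 of 245 cells.

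The deposited log values held no zeros. The lowest was 0.0669, so genes without reads cannot be told from genes at a low level, and low values may have been filled in by the authors' normalization. The 4 plate means of a gene spanned a median of only 0.0766 SD over cells, while the gap between the treatments had a median of 0.167 SD. Plate levels may thus have been equalized before deposit, and differences within plates are then safer than levels across them. No counts were used here, the depth of each cell is unknown, and no limit of detection can be given. Several planned steps needed zeros and could not be carried out. These included a minimum of 1000 detected genes per cell, a minimum of 10% of cells with the gene, gates by detected Cd4 or Cd8a, and shares of cells with a detected gene. In their place all 245 cells and 13576 genes were kept, and the authors' deposited clusters served as classes of cells. Cluster 1 held 16 control and 52 G1T28 cells, cluster 2 held 104 and 45, and cluster 3 held 1 and 27. No doublet caller was run, since it needs counts.

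Gene symbols were taken by identifier from GENCODE M21. Of the 13576 identifiers, 12541 matched and 1035 did not. Another build is named in the processing notes, so no coordinates are given. A total of 215 genes shared an identical profile with another gene, and none of these is named below.

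For each gene the difference in mean log value, G1T28 minus control, was computed over all cells, within each plate and within clusters 1 and 2. Cluster 3 held 1 control cell and allowed no comparison. For each of 28 gene lists the median difference over measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test of the treatment. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a count of 0 was given the limit that 3 counts would set.

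The lists, the cell type markers and the rule for named genes were fixed before the data were examined. The rule took, among genes with the same sign of difference in all 4 plates, the 12 with the largest positive and the 12 with the largest negative difference. Within a cluster it took 6 and 6. In cluster 1 control cells were present on 3 plates, and the rule used these. It also took the 2 members with the largest absolute difference in each list, any member counted, and a fixed set of cell cycle and T cell genes. A set of 11 genes of the T cell receptor complex and its signalling (Cd3d, Cd3e, Cd3g, Trac, Trbc1, Trbc2, Lck, Itk, Cd247, Zap70 and Lat) was chosen after the values had been seen.

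Alternatives left out each plate, weighted plates equally, used a pseudocount of 10, subtracted each cell's mean, or took the mean over list members. Cells were also reclustered by the Leiden method with 2000 variable genes, 30 principal components, 15 neighbours and resolutions of 0.5, 1 and 1.5. Alternatives added after seeing the data were least squares fits with plate, phase or cluster, medians over cells, removal of cluster 3, members with a mean of at least 2, a Cd3 threshold, and clustering without the 1000 genes that differed most within clusters. In cells simulated with the real means and SDs over all cells, 200 of 13576 genes were given known differences. Each gene was drawn alone, with no plates, clusters or animals, so the simulation checks the calculation and not the design. Of the 100 genes with a difference of 0.5, 100% had the right sign over all cells and 98% in each of clusters 1 and 2, with median estimates of 0.51, 0.56 and 0.49 over all cells, in cluster 1 and in cluster 2. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.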

Results

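The series compared CD45+ CD3+ cells sorted from Kras/Trp53 mouse lung tumours of control animals with those of animals given the CDK4/6 inhibitor G1T28. Of the sorted wells, 71 control and 68 G1T28 wells had no values. Plates 1 to 4 gave values for 30, 20, 35 and 36 control cells and for 33, 26, 32 and 33 G1T28 cells. The mean log value per cell had a median of 3.25 in each group. All levels and differences below are natural log values of normalized expression + 1. With 1 sample per treatment there was no replicate check and no test, and "higher" and "lower" describe these cells only.

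Most of the sorted cells carried the transcripts of macrophages. The authors' deposited annotation divided the cells into 3 clusters that held 27.8%, 60.8% and 11.4% of them. Cluster 2 was led by Chil3 (10.91 ± 1.01, SD over cells), a chitinase-like protein of alveolar macrophages, together with Atp6v0d2, Lpl, Slc7a2, Siglec1 and the ribonuclease genes Ear1, Ear2 and Ear10. Lyz2, the lysozyme of myeloid cells, stood at 10.81 in cluster 2 and 10.51 in cluster 1, against 7.50 ± 3.13 in cluster 3. Cluster 1 was led by Itgam (5.57 ± 1.99), the integrin CD11b, with the chemokine receptors Ccr2 and Ccr5 and the matrix genes Thbs1, Vcan and Fn1. By the 12 fixed macrophage or monocyte markers, 7 were highest in cluster 1, 5 in cluster 2 and 0 in cluster 3. Clusters 1 and 2 are called macrophage-like on that basis.

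T cell genes were highest in cluster 3. Its leading genes included Cxcr6 (5.43 ± 1.43), Tcf7 (4.75 ± 1.05), Itk, Trbc2, Cd3e (4.99 ± 0.78), Cd226 and Zap70, and it is called T cell-like. All 7 measured markers of naive or central memory T cells, Tcf7, Lef1, Sell, Ccr7, Il7r, S1pr1 and Satb1, were highest there. Cd4 averaged 3.90 in cluster 3, 2.73 in cluster 1 and 2.29 in cluster 2. Cd8a averaged 2.98, 1.82 and 1.92. The median cell's mean over 11 T cell receptor genes was 4.71 in cluster 3, 2.96 in cluster 1 and 2.08 in cluster 2. Macrophage transcripts were present in cluster 3 too. In 16 of its 28 cells the mean of the 12 macrophage markers exceeded that of the T cell receptor genes, as it did in 100% of the cells of clusters 1 and 2. Clusters 1 and 2 together made up 88.6% of the cells (95% interval 83.9 to 92.3).

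**Figure D1:**
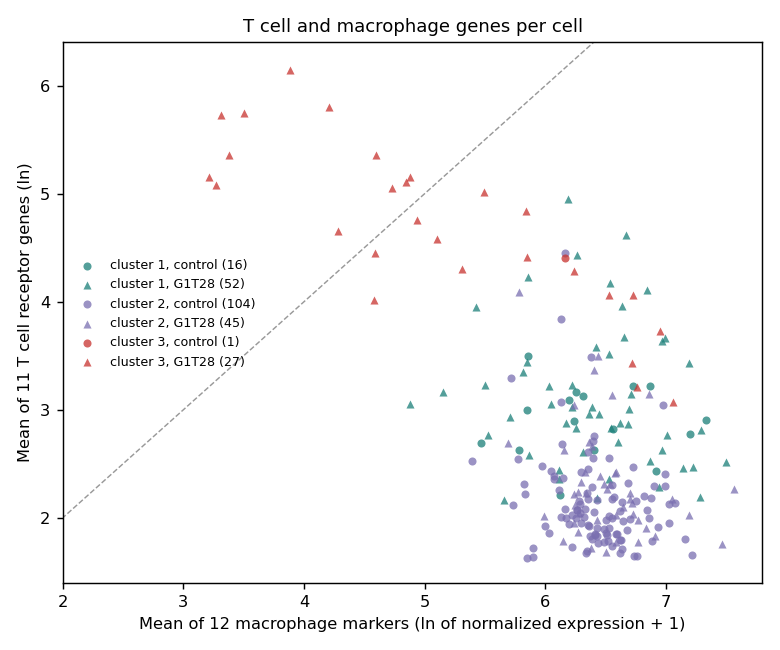
Each point is a cell, with its mean over 12 macrophage markers on the x axis and its mean over 11 T cell receptor genes on the y axis, both in natural log units. Colours are the 3 deposited clusters, circles control cells and triangles G1T28 cells. The dashed line marks equal means, and 12 of the 28 cells of cluster 3 lie on or above it, with no cell of clusters 1 and 2.

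The makeup of the sorted cells differed between the treatments. Cluster 2, with the alveolar macrophage genes, held 86% of control cells (interval 78.5 to 91.6) and 45 G1T28 cells (36.3%, interval 27.8 to 45.4). Cluster 1 held 16 control cells (13.2%, interval 7.75 to 20.6) and 52 G1T28 cells (41.9%, interval 33.1 to 51.1). The T cell-like cluster 3 held 1 control cell (0.826%, interval 0.021 to 4.52) and 27 G1T28 cells (21.8%, interval 14.9 to 30.1). On plates 1 to 4 cluster 3 held 3 of 33, 4 of 26, 10 of 32 and 10 of 33 G1T28 cells. The control cells of these plates numbered 1 of 30, 0 of 20, 0 of 35 and 0 of 36 in it. By the limit of 3 counts, the counts of 0 allow shares of up to 15%, 8.57% and 8.33%, while their exact intervals reach 16.8%, 10% and 9.74%. Cluster 1 was the larger under G1T28 and cluster 2 the larger in controls on each plate. All cells had passed a CD45+ CD3+ gate, which can itself set these shares. When the cells were clustered anew without the 1000 genes that differed most between treatments within clusters 1 and 2, the matching T cell-like class held 0.826% of control and 17.7% of G1T28 cells. With all genes and a Leiden resolution of 1 it held 0 and 18 cells (14.5% of G1T28 cells), and at a resolution of 0.5 it was not separated from cluster 1.

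**Figure D2:**
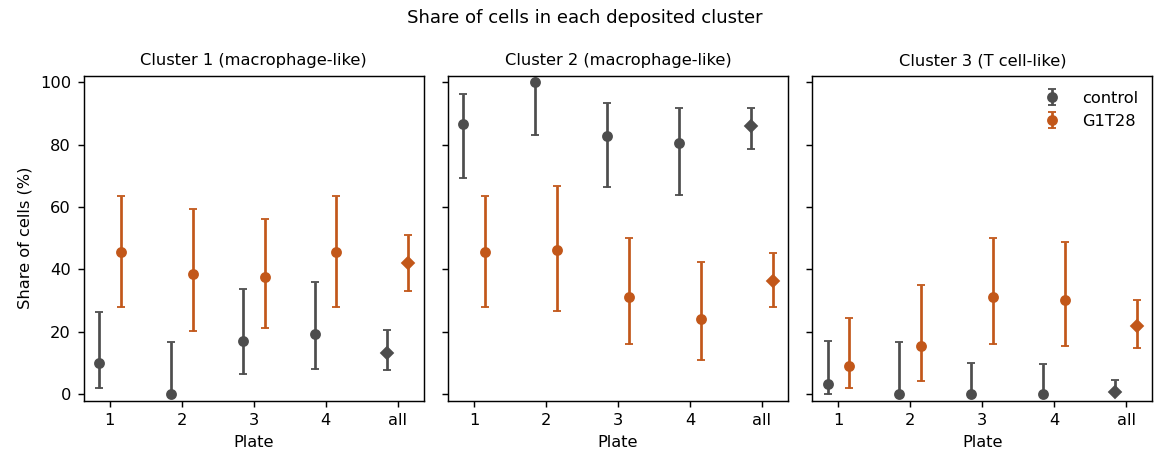
Share of control and G1T28 cells in each deposited cluster, in percent, for plates 1 to 4 (circles) and over all plates (diamonds). Bars are exact 95% intervals for counting error, and the share of cluster 3 over all plates was 0.826% in control and 21.8% in G1T28 cells.

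Of the 12 genes with the largest negative differences over all cells, 9 were among the 10 that lead cluster 2. The fixed macrophage and monocyte list as a whole had a median difference of 0.08, with 6 of 12 members higher. Chil3 (ENSMUSG00000040809.9) averaged 10.36 ± 2.46 in control and 7.37 ± 3.64 in G1T28 cells, a difference of -2.99 that ranged from -4.60 to -1.96 over the plates. The others of the 12 were Net1 (-1.60), Lpl (-1.45), which encodes lipoprotein lipase, Atp6v0d2 (-1.40), Ear10 (-1.37), Ctsk (-1.35), which encodes cathepsin K, Dpep2 (-1.34), Slc7a2 (-1.28), Ear1 (-1.25), Ear-ps2 (-1.24), Ear2 (-1.23) and Perp (-1.20). The Ear genes are near copies of each other, so the split of their reads is uncertain. These differences went in part with the makeup of the cells. Within cluster 1 only 2 of the 12 genes, Dpep2 and Perp, had negative differences. Within cluster 2, 9 of the 12 were negative with a median of -0.15, among them Dpep2 (-0.94), Ctsk (-0.75), Chil3 (-0.71) and Net1 (-0.68). In a fit with cluster as a term, the coefficients of Atp6v0d2 (0.12), Ear10 (0.12), Slc7a2 (0.17), Ear1 (0.001), Ear-ps2 (0.13) and Ear2 (0.13) turned positive, and those of Dpep2 (-0.93), Ctsk (-0.52), Chil3 (-0.49), Net1 (-0.42), Perp (-0.35) and Lpl (-0.11) stayed negative.

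The genes with the largest positive differences were of a mixed kind. Rps3a3 (ENSMUSG00000059751.5), a ribosomal protein gene copy, averaged 2.19 ± 1.18 in control and 3.86 ± 1.33 in G1T28 cells, a difference of 1.67. Genes of the nonclassical MHC class I region followed, H2-Q7 (1.49), H2-T23 (1.38) and H2-Q6 (1.11). Apoe (1.31), which encodes apolipoprotein E, Ece1 (1.18), Ifi203 (1.11), an interferon-inducible gene, and Nsmaf (1.08) were also among the 12. The remaining genes are used by lymphocytes: Itk (1.23) and Rasgrp1 (1.17), of T cell receptor signalling, Gimap6 (1.20) and Ms4a4b (1.10). The differences of all 12 were also positive within cluster 1 (0.38 to 1.99) and within cluster 2 (0.25 to 1.45). Rps3a3 shares 67.2% of its words of 31 bases with Rps3a1 and 72.3% with Rps3a2 in the annotated transcripts, and H2-Q6 shares 18.4% with H2-Q7, so reads of these genes may have been split between copies.

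Lists of genes used by T cells, though not by T cells alone, were higher in the G1T28 group over all cells. The naive and memory list had a median difference of 0.69, with 12 of 12 measured members higher, among them Il7r (3.38 ± 1.11 in control and 4.40 ± 1.31 in G1T28 cells), the interleukin 7 receptor, S1pr1 (0.99) and Tcf7 (0.88). Costimulatory receptors had a median of 0.64, with 6 of 6 members higher, Cd226 (0.80) and Tnfrsf9 (0.76) foremost. NFAT and T cell receptor induced genes had a median of 0.40, with 11 of 13 higher, including Nr4a3 (0.77) and Tnfrsf9. Each of these 3 medians lay above all 10000 random lists and was positive on 4 of 4 plates. The same held for immediate early and dissociation stress genes (median 0.19), a list that shares Egr1 with the NFAT list. Regulatory T cell genes (0.38, 7 of 8 higher, led by Tnfrsf18 and Il2ra), inhibitory receptors (0.17, 6 of 8 higher, led by Entpd1 and Tox) and cytotoxic and effector genes (0.14, 7 of 8 higher, led by Cx3cr1 and Ccl5) lay at percentiles 99.98, 98.7 and 98. The inhibitory receptor median fell to 0.03 when only members with a mean of at least 2 were used. The 11 T cell receptor genes differed by 0.72 to 1.23. Without the cells of cluster 3, the medians were 0.34 for the naive and memory list, 0.36 for costimulatory receptors, 0.35 for NFAT and T cell receptor induced genes and 0.27 for regulatory T cell genes. Inhibitory receptors stayed at 0.16, and cytotoxic genes rose to 0.335. With cluster as a term the medians of these lists were, in the same order, 0.18, 0.22, 0.08, 0.11, 0.08 and 0.02. The cytotoxic median ranged from 0.10 to 0.28 with 1 plate left out and was 0.01 on plate 4. Of the 24 cytotoxic and effector members only 8 were measured, without the granzyme genes or Prf1. Ccl3, Ccl4, Tnf, Zeb2 and Prdm1 were highest in the macrophage-like cluster 1 (Ccl3 at 4.78, against 2.39 in cluster 3). Ccl5, Id2 and Cx3cr1 were highest in cluster 3. In the NFAT list, Egr1, Egr2, Irf4, Tnf, Tnfrsf9, Nr4a2, Nfatc1 and Rcan1 were highest in cluster 1. Rcan1 averaged 4.09 there, against 1.88 in cluster 3. Nr4a1, Nr4a3, Cd69, Myc and Il2ra were highest in cluster 3. Of the measured inhibitory receptors only Tigit and Tox were highest in cluster 3. Il2, Ifng, Cd40lg, Pdcd1 and Ctla4 were not measured. These lists are thus no measure of T cell cytotoxicity, activation or exhaustion alone.

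Interferon and MHC class I genes were higher in the G1T28 group. The interferon response list had a median of 0.34 with 13 of 14 members higher, led by Irf7 (0.62) and Zbp1 (0.60), and plate values from 0.27 to 0.40. The MHC class I presentation list had a median of 0.27 with 8 of 9 members higher. Its largest differences were those of H2-K1 (0.79), a classical MHC class I heavy chain, and Nlrc5 (0.50), its transcriptional activator. B2m, the light chain, differed by 0.39. Both medians lay above all 10000 random lists. They were 0.17 and 0.16 with cluster as a term. The strain was a mixed background and no animals were named. Strain variants of H2-K1, H2-Q7, H2-T23 and H2-Q6 can therefore not be told apart from an effect of G1T28.

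**Figure D3:**
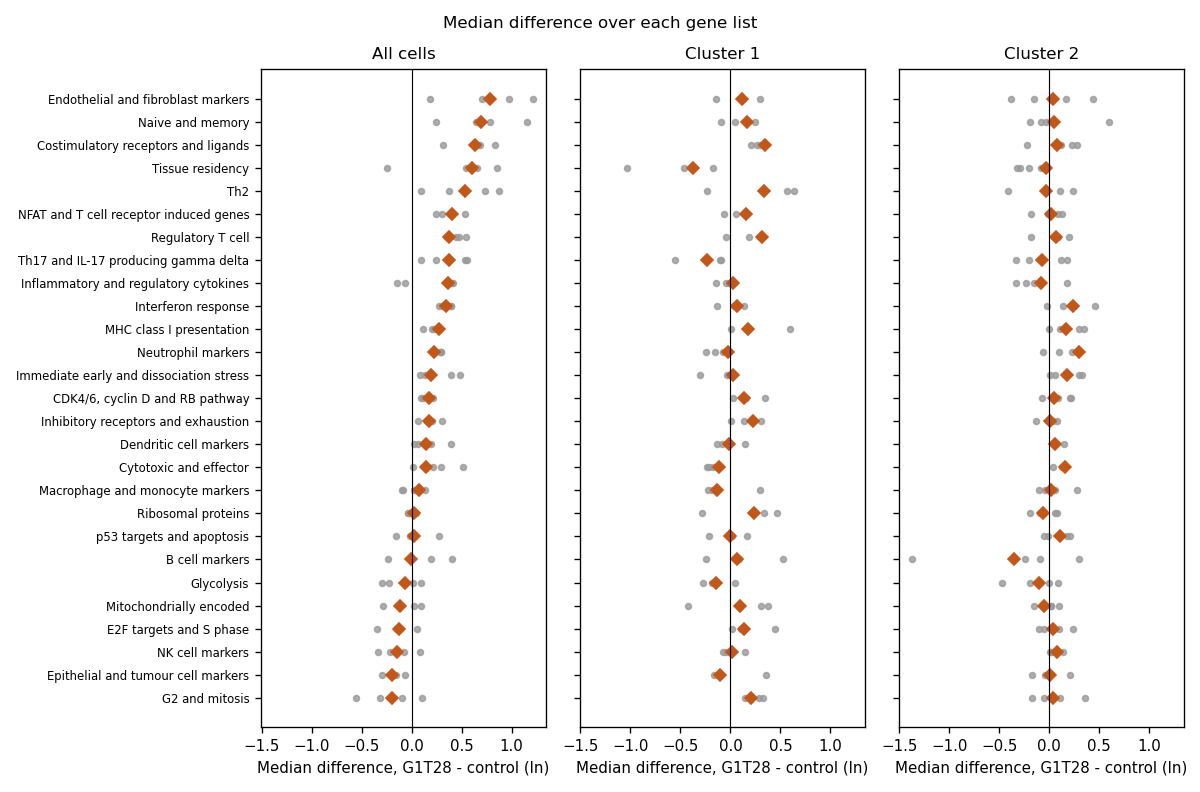
Median difference, G1T28 minus control in natural log units, over the measured members of each of 27 gene lists, for all cells and within clusters 1 and 2. Diamonds are pooled cells and grey circles the plates with cells of both groups. The naive and memory list stands at 0.69 over all cells, 0.17 in cluster 1 and 0.05 in cluster 2.

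The inhibitor acts on the cell cycle, so cycle genes and phases were compared next. Over all cells fewer G1T28 cells were assigned to S or G2M phase in the authors' deposited calls, 21 cells (16.9%, interval 10.8 to 24.7) against 35 control cells (28.9%, interval 21 to 37.9). By plate the shares were 12.1%, 23.1%, 15.6% and 18.2% of G1T28 cells and 23.3%, 30%, 14.3% and 47.2% of control cells, so plate 3 went the other way and plate 4 held the widest gap. Without plate 4 they were 16.5% and 21.2%. The share in S phase alone was higher under G1T28 on plates 1 to 3 (12.1%, 15.4% and 9.38% against 6.67%, 5% and 5.71%) and lower on plate 4 (9.09% against 38.9%). The share in G2M phase alone was lower under G1T28 on plates 1 to 3 (0%, 7.69% and 6.25% against 16.7%, 25% and 8.57%). On plate 4 it was 9.09% against 8.33%, and over all plates 5.65% against 13.2%. The E2F target and S phase list had a median difference of -0.13 (percentile 1.46, 22 of 27 members lower), led by Cdc45 (-0.55) and Slbp (-0.46). The G2 and mitosis list had a median of -0.20 (percentile 0.65, 11 of 12 lower), led by Bub1b (-0.63) and Mki67 (-0.31). Each was negative on 3 of 4 plates and positive on plate 1 (0.06 and 0.11). With 1 plate left out the E2F median ranged from -0.215 to -0.08 and the G2 and mitosis median from -0.26 to -0.14. The phases followed the clusters. Cells called S or G2M made up 34.9% of cluster 2 (52 cells), 5.88% of cluster 1 (4 cells) and none of the 27 G1T28 cells of cluster 3. That count of 0 allows a share of up to 11.1% by the limit of 3 counts, and its exact interval reaches 12.8%.

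Within clusters 1 and 2 the direction seen over all cells was not found in the pooled share of S and G2M together. Nor was it found in the pooled medians of the cycle lists. In cluster 2, 17 of 45 G1T28 cells (37.8%, interval 23.8 to 53.5) and 35 control cells (33.7%, interval 24.7 to 43.6) were called S or G2M. By plate these shares were 26.7%, 41.7%, 40% and 50% of G1T28 cells and 26.9%, 30%, 17.2% and 58.6% of control cells. The share in G2M phase alone was lower under G1T28 in cluster 2, 11.1% (interval 3.71 to 24.1) against 15.4% (9.06 to 23.8). By plate it was 0%, 16.7%, 20% and 12.5% of G1T28 cells and 19.2%, 25%, 10.3% and 10.3% of control cells. The share in S phase alone was 26.7% against 18.3%, higher on plates 1 to 3 and lower on plate 4 (37.5% against 48.3%). The E2F list had a median difference of 0.04 and the G2 and mitosis list of 0.03 in cluster 2, less than their SDs over plates of 0.15 and 0.23. In cluster 1, 4 of 52 G1T28 cells and 0 of 16 control cells were called S or G2M. The latter allows up to 18.75% by the limit of 3 counts, and its exact interval reaches 20.6%. Both lists were higher in the G1T28 cells of cluster 1, with medians of 0.14 (percentile 97.6, SD over plates 0.23) and 0.20 (percentile 98.8, SD 0.09). The E2F median is thus less than its SD, and it ranged from 0.07 to 0.18 with 1 plate left out. The G2 and mitosis median was 0.11 when medians over cells were used. Ribosomal protein genes, which are not specific to the cycle, were higher in cluster 1 by a median of 0.24 (percentile 98.6, 18 of 18 higher, 2 of 3 plates). Mcm2, a helicase subunit of S phase, averaged 2.97 in control and 3.92 in G1T28 cells there. Phase calls per cell depend on the deposited normalization, and no cycling rate is read from them.

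Cdk4 and Cdk6, the kinases inhibited by the compound, differed by -0.07 and -0.13. Cdk4 averaged 4.59 ± 1.29 in control and 4.52 ± 1.27 in G1T28 cells, and Cdk6 4.59 ± 1.32 and 4.46 ± 1.37. Rb1, their substrate, averaged 3.39 ± 1.26 and 3.56 ± 1.19. The CDK4/6, cyclin D and RB list had a median difference of 0.17 (percentile 99.8, 10 of 13 higher, 4 of 4 plates), led by Ccnd3 (0.46) and E2f3 (0.36). The median was 0.10 without plate 3, 0.11 with a pseudocount of 10, 0.09 with medians over cells and 0.10 with cluster as a term. In cluster 2 the median was 0.05, with Ccnd2 (0.74) and Ccnd3 (0.55) higher. In cluster 1 it was 0.13, with Ccnd3 (0.64) and Rbl1 (0.43) foremost. Cyclin D genes encode the partners of Cdk4 and Cdk6. Nfatc1 averaged 3.67 ± 1.09 and 3.77 ± 1.17, and Nfatc3 3.36 ± 1.10 and 3.71 ± 1.05. Cd4 and Cd8a differed by 0.49 and 0.27 over all cells, by 0.43 and 0.20 in cluster 1 and by -0.13 and 0.09 in cluster 2. Foxp3, Ifng, Gzmb, Pdcd1, Ctla4 and Il2 were looked for but not found among the genes with a symbol. The regulatory T cell list was thus without Foxp3 and Ctla4.

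Within cluster 2, the 45 G1T28 cells had higher levels of H2-T23 (5.64 ± 0.99 against 4.19 ± 1.07 in control cells, a difference of 1.45), Slc39a2 (1.16), a zinc transporter, Plau (1.10), the urokinase plasminogen activator, H2-Q7 (1.02), Adsl (0.90) and Mdn1 (0.87). Fkbp5, a glucocorticoid-induced chaperone, was lower (4.09 ± 1.59 against 5.22 ± 1.31, a difference of -1.14), as were Birc3 (-1.11), Klhl24 (-0.91), ENSMUSG00000087313.2 (-0.89), Selenop (-0.84) and Megf9 (-0.83). The signs were the same on 4 of 4 plates by rule, so the shared sign is no evidence of agreement, and sizes varied. Across 13348 genes the differences within cluster 2 agreed little between plates, with correlations of -0.006 to 0.21 for pairs of plates. H2-T23 differed by 2.08, 0.96, 2.32 and 0.05 on plates 1 to 4, and Fkbp5 by -1.57, -2.69, -0.05 and -0.06. Plau and Adsl differed by only 0.13 and 0.03 on plate 4. With 1 plate left out they ranged from 0.67 to 1.35 and from 0.50 to 1.12. The interferon list was higher (median 0.24, percentile 99.99, 13 of 14 members), led by Oas1a (0.53) and Irf9 (0.40), with a plate 4 value of -0.02. The MHC class I list was higher (0.17, percentile 97.6, 9 of 9 members), led by H2-K1 (0.75) and B2m (0.46). Its median was 0.001 on plate 1 and ranged from 0.11 to 0.26 with 1 plate left out. Naive and memory T cell genes differed by a median of 0.05 and NFAT and T cell receptor induced genes by 0.02, with plate values on either side of 0. The 11 T cell receptor genes had a median of 0.14, from -0.06 to 0.46 (Cd3d).

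Within cluster 1, with 52 G1T28 and 16 control cells, Plet1 had the largest difference (6.45 ± 1.54 against 4.24 ± 2.67, a difference of 2.22), followed by Rps3a3 (1.99), H2-Q7 (1.77), H2-T23 (1.66), Qars (1.55) and Tbl1xr1 (1.47). Ecm1 (-1.52), the chemokine gene Ccl9 (-1.51), Zyx (-1.37), Atp13a2 (-1.30), Zmym5 (-1.30) and Zfp36 (-1.26), an mRNA decay factor, were lower. H2-K1 (0.78) and B2m (0.51) led the MHC class I list, whose median was 0.18 (percentile 85, 8 of 9 members higher), with plate values of 0.59, 0.003 and 0.17 and a range from 0.08 to 0.27 with 1 plate left out. The interferon list had a median of 0.06 (percentile 73.5). Costimulatory receptors were higher (0.34, percentile 99.4, 3 of 3 plates), led by Cd27 (0.77) and Tnfrsf9 (0.71), with 0.19 when medians over cells were used. Some other T cell genes moved with them. Regulatory T cell genes had a median of 0.32 (percentile 99.7, 2 of 3 plates, 0.10 when medians over cells were used), and the 11 T cell receptor genes one of 0.18, up to 0.58 for Itk. Other T cell lists went the opposite way on 3 of 3 plates. These were tissue residency (-0.37, 0 of 3 members higher), Th17 (-0.23, 0 of 3 higher) and cytotoxic and effector genes (-0.11). The 16 control cells came from 3 plates, with 3, 6 and 7 cells, and plate 2 had none. A cell's mean over the 11 T cell receptor genes reached 4.95 in the G1T28 cells of cluster 1 and 3.49 in its control cells. The median in cluster 3 was 4.71. Whether a few cells with high T cell genes, or doublets, made the higher T cell medians of cluster 1 was not tested.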

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

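Leaving out plates was planned, and the medians over cells and the tests of the macrophage pattern were chosen after the result was seen. The only result that met a rule for a closer look was the cytotoxic and effector list, 8 of whose 24 members were measured. The granzyme genes and Prf1 were not among them. The median difference of the list was negative on each of the 3 plates with cells of both groups in cluster 1 and positive on each of the 4 plates in cluster 2, so the clusters went opposite ways. The pooled medians were -0.11 in cluster 1, led by Cx3cr1 (5.08 in control and 3.91 in G1T28 cells), and 0.16 in cluster 2, led by Ccl3 (4.08 and 4.67). The difference between the clusters was not tested. Without plate 4 the median of cluster 1 was 0.054, and medians over cells gave 0.006, so the opposite sign rests on few control cells. In cluster 2 the same alternatives gave 0.095 and 0.072.

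The pattern that most needs following up is that macrophage genes lead most cells of a CD3+ sort. Gene identifiers out of step with the values are argued against by the T cell receptor genes, which went together across cells with a median pairwise correlation of 0.76 over 11 genes, against 0.001 for random pairs. T cells with free or adhering macrophage RNA and macrophages inside the CD3 gate cannot be told apart. T cell receptor genes were lower in cluster 2 than in cluster 3 by a median of 2.45 (2.13 to 2.90) and lower in cluster 1 by 1.68 (1.10 to 1.92), but cluster 3 is set apart by these same genes. The macrophage marker mean exceeded the T cell receptor gene mean in 100% of the cells of clusters 1 and 2, but these clusters were named by the same markers, so neither value decides. The CD45+ CD3+ gate should have removed macrophages, autofluorescence and doublets were not tested, and no biological explanation was tested.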

How the results depend on the processing

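The alternatives that leave out plates, weight plates equally, use a pseudocount of 10, subtract each cell's mean, take the mean over members or recluster the cells were planned, and the least squares fits, medians over cells, removal of cluster 3, the filter on low members, the Cd3 threshold and clustering without 1000 genes were chosen after seeing the data. A value counted as kept when it moved by less than its SD over plates, or stayed in its 95% interval for shares. It counted as reversed when the main value exceeded its SD over plates and the sign changed. Many list medians lie within that SD, so a change of sign was more frequent, at 25, 49 and 33 list values over all cells, in cluster 1 and in cluster 2. Of the values of the 27 lists under all alternatives, 36 moved and 5 reversed over all cells, 18 and 3 in cluster 1, and 12 and 0 in cluster 2. Of those of the named genes, 29 moved and 6 reversed over all cells, and 3 and 4 moved in clusters 1 and 2, with 0 reversed. Of 74 shares 64 were kept. The alternatives that needed zeros (cell filters, detection filters, detection shares, gates and the fit with detected genes) could not be run, and the depth of the cells is unknown. No paired analysis was possible because the numbers in the labels name wells, not animals, so none could be paired by animal. Plates hold both groups and served as blocks in the differences within plates and in the fits with plate. The plate means of a gene spanned a median of only 0.0766 SD over cells. Over all cells, fits with plate and clustering with plate means removed could thus change little and are weak checks.

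Cluster as a term moved the most, 13 of 27 lists and 13 of 24 named genes, as its construction removes the unequal makeup of the groups. Over all cells it gave 0.057 for the E2F list, 0.081 for NFAT and T cell receptor induced genes, 0.18 for naive and memory, 0.17 for interferon response and 0.16 for MHC class I. The cycle lists thus turned positive, with 0.043 for G2 and mitosis, though neither main value exceeded its SD over plates, and so did NK cell markers (0.054). By the rule above it reversed the Th17 (-0.081), tissue residency (-0.13) and cytokine (-0.013) lists, and Atp6v0d2 (0.12), Ear10 (0.12), Slc7a2 (0.17), Ear1 (0.001), Ear-ps2 (0.13) and Ear2 (0.13). Without cluster 3 cells, tissue residency (-0.003) and epithelial and tumour markers (0.13) reversed. For the remaining changes the cause was not tested. A pseudocount of 10 gave 0.28 for interferon response. Leaving out plates moved MHC class I between 0.20 and 0.32 over all cells, and medians over cells gave 0.20. Medians over cells gave 0.11 for G2 and mitosis and -0.024 for NFAT and T cell receptor induced genes in cluster 1. In the cytotoxic list of cluster 1 they gave 0.006, and leaving out plates gave -0.239 (without plate 3) to 0.054 (without plate 4).

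The share of G1T28 cells in cluster 3 was 14.5% at Leiden resolutions of 1 and 1.5 and with plate means removed, since 9 cells then joined cluster 1, and 0% at a resolution of 0.5, where cluster 1 took 64.5%. The control share was 0% at resolutions of 0.5 and 1 and with plate means removed, and 0% to 1.18% with plates left out. A mean of Cd3d, Cd3e and Cd3g above 4 held 3.31% of control and 21% of G1T28 cells, but 3 and 15 cells lay between 3.5 and 4.5. These were in part other cells than those of cluster 3, which held 1 of the 4 control and 19 of the 26 G1T28 cells above 4. The S or G2M share of control cells in cluster 2 ranged from 24% without plate 4 to 40%, and that of G1T28 cells from 35.1% to 43.3%.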

Other observations

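Of the tests in this part, the correlation between plates, the count of lost wells and the 8 glucocorticoid-induced genes in cluster 2 had their predictions written beforehand, and the others were chosen after the result was seen. Several gene groups not described so far differed within the macrophage-like clusters. In cluster 2, immediate early and dissociation stress genes had a median difference of 0.17 (percentile 99.7, positive on 4 of 4 plates), though members went both ways, with Fosb higher (4.42 in control and 5.24 in G1T28 cells) and Dusp1 lower (7.33 and 6.68). The median was 0.01, 0.29, 0.33 and 0.06 on plates 1 to 4, and it ranged from 0.10 to 0.27 with 1 plate left out. Lyz2 (10.58 and 11.33) and Itgax (6.52 and 7.11), which encodes CD11c, were higher on 4 of 4 plates. The antigen presentation genes Cd74 (8.71 and 8.06) and H2-Aa (8.03 and 7.67), of MHC class II, were lower on 3 of 4 plates and formed part of the B cell marker list, whose median was -0.36, with 0.29 on plate 3, -1.38 on plate 4 and a range from -0.57 to -0.09 with 1 plate left out. Rgs1, a regulator of G protein signalling, was lower in both clusters, at 6.65 and 5.95 in cluster 2 and 6.88 and 6.23 in cluster 1. Glycolysis genes had medians of -0.14 in cluster 1 and -0.11 in cluster 2 (percentiles 2.61 and 3.19), but plates differed in sign (-0.18, 0.05 and -0.28 on plates 1, 3 and 4 in cluster 1, and -0.004, -0.48, 0.09 and -0.19 on plates 1 to 4 in cluster 2), and without plate 4 the median of cluster 1 was 0.001. Pfkp was higher in both (0.94 and 0.57). In cluster 1 Cxcl2 (6.85 and 6.21) was lower, and Slc2a1 (4.07 and 4.85), the glucose transporter GLUT1, was higher.

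The other lists had these medians over all cells. The Th17 list stood at 0.37 (3 members measured), Th2 at 0.54 (2 members), tissue residency at 0.61 (3 members), inflammatory and regulatory cytokines at 0.36 (negative on plates 1 and 2, and 0.10 to 0.42 with 1 plate left out), dendritic cell markers at 0.15 and neutrophil markers at 0.22. The p53 list stood at 0.02, glycolysis at -0.06, immediate early genes at 0.19, ribosomal proteins at 0.03, mitochondrially encoded genes at -0.11, B cell markers at -0.01, NK cell markers at -0.14, epithelial and tumour markers at -0.20, and macrophage and monocyte markers at 0.08, with 6 of 12 members higher. The direction of the macrophage median did not hold, with -0.26 for the mean over members, -0.04 without plate 4 and 0.30 for medians over cells. Of the endothelial and fibroblast list only Pecam1 (0.78) was measured, and of the 7 erythroid markers none was. With cluster as a term the tissue residency, cytokine, Th17, B cell, epithelial and macrophage medians were -0.13, -0.01, -0.08, -0.06, -0.05 and -0.01.

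The T cell-like cluster held 27 G1T28 cells and 1 control cell. A difference between plates is argued against, since its share was higher under G1T28 on 4 of 4 plates. Unequal loss of wells stays open: of the 71 control wells without values, 33 with T cell-like cells would level the shares if the others held no cell, and 41 if all held cells and the lost G1T28 wells had the share of the measured ones. Position on the plate or separate sorting of the treatments cannot be told apart from G1T28, because 0 of the 12 plate columns held cells of both treatments. A change in the tumours under the inhibitor stays among the open explanations, untested without animals named.

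Rps3a3 and H2-T23 differed by plate in cluster 2. The Rps3a3 difference was -0.01, 3.28, 0.19 and 2.65 on plates 1 to 4, and that of H2-T23 was 2.08, 0.96, 2.32 and 0.05. Their ranges were 2.54 and 2.21 SD over cells. On plate 4 the lowest Rps3a3 value of the 8 G1T28 cells (4.23) lay above the highest of the 29 control cells (2.95). On plate 1 the Rps3a3 means were 2.70 in G1T28 and 2.71 in control cells. Both genes were picked for these ranges, so the ranges cannot decide whether a response to G1T28 was alike on every plate. If plates 1 and 3, and 2 and 4, shared animals, differences across 13348 other genes were predicted to correlate more within these pairs. The mean correlation within them minus that across them was -0.047, with the highest value, 0.21, between plates 1 and 2. The prediction was thus not met. Differences between animals at few genes would hardly change a correlation across 13348 genes, so these pairs and other arrangements of animals stay open. The explanation by shared animals first spoke of different animals on different plates. It was narrowed to these pairs after the result, while its prediction was left as written. Reads shared between Rps3a1 and its copies may contribute. The G1T28 minus control difference of Rps3a1 was lower on plates 2 and 4 (-0.81 and -0.40) than on plates 1 and 3 (-0.185 and 0.13), with -0.58 between their means. The differences of Rps3a3 and Rps3a2 were higher on plates 2 and 4. A strain variant in a mixed background could not be examined without reads.

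A hypothesis was that glucocorticoid-induced genes were lower under G1T28, since Fkbp5 (-1.14), Klhl24 (-0.91), Txnip (-0.81) and Dusp1 (-0.65) were lower in cluster 2. Of 8 other glucocorticoid-induced genes not looked at before, 6 were lower in cluster 2, among them Tsc22d3 (6.03 in control and 5.43 in G1T28 cells) and Klf9 (3.84 and 3.29), while Pdk4 and Mt2 were higher. Their median of -0.16 lay at percentile 1.48 of random lists, which is consistent with a weaker glucocorticoid response. By plate the median was -0.50, -0.40, -0.09 and 0.11, so the effect rests on plates 1 and 2. In cluster 1 the median was -0.43 (percentile 0.01), with -0.83, -0.37 and -0.16 on plates 1, 3 and 4. Handling of the animals before tissue collection was not recorded in the labels, and it may differ between the groups.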
